A study of Mus musculus with 9 samples.

How the data were processed

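Gene expression was measured in mouse bone marrow cells by QuantSeq, a 3' tag method in which a read is primed near the polyadenylation site, so that a count reflects transcripts and not their length. Per the labels' protocols, lineage-depleted marrow cells carrying floxed Runx2 and a tamoxifen-inducible Cre were given a retrovirus for KMT2A-MLLT1, a leukaemia fusion protein also called MLL-ENL, and were passed through serial plating in methylcellulose at intervals of 7 days. Libraries were made from 500 ng of RNA. The 9 libraries form 3 groups of 3. BM progenitor RNA was taken before the first replating. Transformed cells came from later suspension culture and were given either ethanol (Runx2wt) or 4-hydroxytamoxifen (4-OHT), which activates Cre, at 400 nM over 24 hours (Runx2ko). The labels leave open whether the BM progenitor cells carried the fusion. The extraction protocol in the labels speaks of T-ALL cells, which no other label mentions, so it is not settled which cells that protocol refers to. Culture form and passage differ between BM progenitor and transformed cells, and 4-OHT and Cre activity go with the Runx2ko group in every library, so the comparisons measure these together. The labels name the samples as independent biological replicates.

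The authors deposited raw counts per Ensembl gene and a table of normalized values. The raw table holds 21159 genes, of which 1188 had no count in any library. The authors' normalized values were the raw counts divided by 1 constant per library, as found by dividing the tables; how the constants were made is not given in the sources used here. Per the submitters' processing notes, FastQC, STAR and DESeq2 were used, with the build GRCm38; their versions, the counting program and the annotation release are not given in the sources used here. Whether counting used strand is likewise not stated, so overlapping and antisense genes may share reads, as may members of multigene families such as the Ear ribonucleases. Symbols came from a GENCODE annotation of the same build and matched 21042 of the 21159 identifiers.

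Library totals ran from 3118594 to 5348177 counts and 14377 to 15634 genes had a count. The 20 most abundant genes took 8.8% to 10.4% of a library and mitochondrial genes 1.7% to 2.2%. No libraries of a group agreed within sampling noise (chi-square per gene at least 4.54), so each counted as 1 sample.

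The raw counts were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F-test, with TMM factors and the filterByExpr filter, which left 11196 genes. All 9 libraries shared 1 estimate of the spread. Genes passed at a Benjamini-Hochberg adjusted p under 0.05. Standard errors of log2 fold changes were derived from the F statistic. CPM values used the TMM-scaled library sizes. Where every library of a group had 0 counts, a fold is given as a bound against a floor of 3 counts over that group; such floors cover counting error only. Gene lists written before the data were examined were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with at least 5 tested members, which left 27 lists. Sex-linked genes served as a check of the samples and were not tested as a list. Alternatives were DESeq2 1.42.0, limma-voom, other size factors and filters, only the compared libraries, a replicate block, a minimum fold, the authors' normalized values with a pseudocount of 1, an estimated correlation, fry, and leaving out each library in turn. Fits without Runx2ko replicate 1 for the comparison of Runx2wt with BM progenitor were added after seeing the data.

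Genes are named by a rule fixed beforehand: Runx2 and a panel of 15 further genes, up to 8 largest rises and falls of passing genes with at least 10 CPM and non-overlapping groups, and up to 3 members of each list, or the most highly expressed member where none passed. The rule was repeated for the fit without Runx2ko replicate 1. Not every gene that the rule chose is printed.

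The fit was tested on simulated counts of 11196 genes, with a seeded set of genes changed. Counts were drawn from the real library sizes and spread, at each gene's mean over all 9 libraries. For Runx2ko against Runx2wt the fit recovered 7.7% of 65 genes changed by 2-fold, 69.4% of 62 changed by 4-fold and 97% of 66 changed by 16-fold. For Runx2wt against BM progenitor it recovered 18.8%, 69.7% and 88.9%, and for Runx2ko against BM progenitor 10.3%, 57.8% and 96.8%. Genes were drawn independently, so these shares need not hold for real libraries whose genes move together.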

Results

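The data were 9 libraries of 3' tag counts from mouse bone marrow cells, 3 each of BM progenitor, transformed Runx2wt and transformed Runx2ko. Total counts were 5348177, 3555621 and 4476900 in BM progenitor replicates 1 to 3, 5276311, 3808944 and 3767898 in Runx2wt and 3118594, 5316878 and 3829797 in Runx2ko. Runx2ko replicate 1 stood apart. Its log2 CPM correlated at 0.793 to 0.816 across genes with the other transformed libraries, whereas Runx2wt libraries correlated at 0.934 to 0.955 with Runx2ko replicates 2 and 3 and at 0.945 to 0.959 with each other. Mast cell and basophil genes averaged 4.35 log2 units above the Runx2wt mean in this library, against a range of -0.67 to 1.21 in the other transformed libraries and 1.99 to 2.15 in BM progenitor, and monocyte and macrophage genes averaged -1.99, against -0.24 to 0.34 and -0.12 to 0.13.

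**Figure D1:**
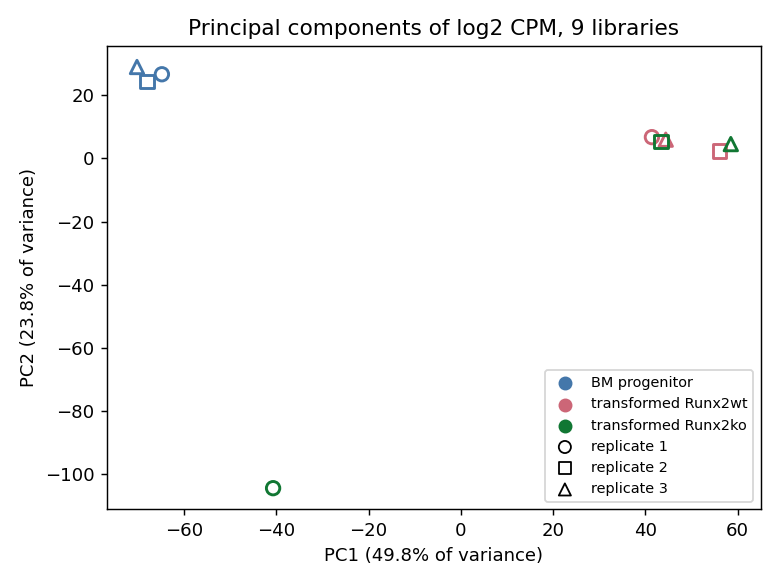
Principal components of log2 CPM, with each point a library, colour giving the group, shape the replicate and axes the share of variance. PC1 (49.8%) parts BM progenitor from 5 of the 6 transformed libraries, and Runx2ko replicate 1 lies alone at -104.4 on PC2 (23.8%).

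The gene targeted by the design, Runx2 (ENSMUSG00000039153, GRCm38 chromosome 17, 44495987 to 44814797, minus strand), encodes a RUNX transcription factor known for its part in bone formation. It was counted at 53.3, 46.7 and 58.8 CPM in BM progenitor, at 159.4, 178.8 and 131.0 CPM in Runx2wt and at 21.0, 120.1 and 134.7 CPM in Runx2ko. The labels do not name the floxed exon, so 3' tags may lie outside the deleted part and these values do not check the deletion. In the libraries labelled Runx2ko, replicate 3 lay within the range of Runx2wt and replicate 2 just below it, so directions given for Runx2ko are those of libraries under that label. Runx2 differed between Runx2ko and Runx2wt by -0.76 log2 units (SE 0.51), which did not pass (edgeR adjusted p = 0.725; -0.30 without Runx2ko replicate 1, adjusted p = 0.741).

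The comparison of transformed Runx2wt with BM progenitor cells asked what differs once the fusion has transformed the culture. Hoxa9 and Hoxa10, homeobox genes of the Hoxa cluster, and their cofactor Meis1 rose. Hoxa9 (ENSMUSG00000038227) was at 471.5 ± 41.5 CPM in Runx2wt and 36.5 ± 9.88 CPM in BM progenitor (SD, n = 3 each), a log2 fold change of 3.69 (SE 0.32, edgeR adjusted p = 0.000615). Hoxa10 rose by 6.22 log2 units and Meis1, a partner of Hox proteins, by 3.05. Of 23 tested KMT2A-fusion target genes, 12 rose, 1 fell and 10 did not pass; adjusted over the list alone, 15 rose and 2 fell. The number that rose was 7 without BM progenitor replicate 3, at least 9 without each other compared library, and 15, with 3 that fell, without Runx2ko replicate 1. The camera call of this list (adjusted p = 3.34e-13) was lost with an estimated correlation (adjusted p = 0.115) but held with one without Runx2ko replicate 1 (adjusted p = 0.038). Spp1, which encodes osteopontin and is 1 of 2 genes that rose among 3 tested skeletal targets of Runx2, rose by 5.60 log2 units (SE 0.90); 1 rose without BM progenitor replicate 3 and 3 of 4 without Runx2ko replicate 1.

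Eosinophil genes fell. Of 9 tested, 8 fell and none rose, both over all genes and adjusted over the list alone, and this camera call (adjusted p = 2.77e-36) held with an estimated correlation (adjusted p = 0.000568, and 0.0163 without Runx2ko replicate 1). Prg2, the eosinophil major basic protein, went from 1402 ± 227.2 to 1.70 ± 1.16 CPM, and Ear6, an eosinophil-associated ribonuclease, fell by 8.86 log2 units (SE 0.45). Epx, eosinophil peroxidase, had 0 counts in the 3 Runx2wt libraries and was at least 189-fold lower. Mpo, the myeloperoxidase of primary granules, went from 2721 ± 482.2 to 9.35 ± 3.97 CPM, a log2 fold change of -8.16 (SE 0.60, edgeR adjusted p = 0.000345). Of 17 primary granule genes 4 fell and 1 rose, and Elane, neutrophil elastase, was at 374.9 ± 240.9 CPM against 743.8 ± 145.6 CPM and did not pass. Of 25 late neutrophil genes 3 fell and 1 rose, and log2 fold changes were -6.91 for Camp and -6.72 for Ltf, both genes of secondary granules. Of 17 dendritic cell and MHC class II genes 7 fell and none rose, among them Siglech and Batf3. Of 21 stem and progenitor genes 5 fell and 2 rose, with a log2 fold change of -6.32 for Hlf, a transcription factor of stem cells. Adjusted over the list alone, 6 primary granule genes fell and 2 rose, 9 late neutrophil genes fell and 2 rose, 7 dendritic cell genes fell, and 8 stem genes fell and 4 rose. With an estimated correlation the adjusted p was 0.603 for the primary granule, late neutrophil and stem lists and 0.157 for the dendritic cell list. These counts changed when a library was left out, and a fit without a compared library also has fewer libraries in a group. Without BM progenitor replicates 1, 2 and 3, Runx2wt replicates 1, 2 and 3 and Runx2ko replicate 1 in turn, the numbers that fell were 3, 3, 3, 6, 3, 3 and 8 for primary granule genes, 2, 2, 2, 2, 3, 3 and 11 for late neutrophil genes, 3, 3, 3, 4, 3, 5 and 8 for dendritic cell genes, 2, 1, 1, 4, 1, 3 and 13 for stem genes and 6, 6, 6, 7, 7, 7 and 8 for eosinophil genes. Without Runx2ko replicate 1, 2 primary granule, 3 late neutrophil, 1 dendritic cell and 4 stem genes rose.

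Among metabolic and growth genes, 21 of 74 ribosomal protein genes rose and none fell, by sizes such as 0.93 log2 units for Rpl13a, and 6 of 23 glycolysis genes rose and none fell, with Aldoc rising by 3.32. Cell cycle genes fell for 7 of 37 tested and cholesterol synthesis genes for 6 of 24. Adjusted over the list alone, 29 ribosomal and 7 glycolysis genes rose, and 15 cell cycle and 17 cholesterol genes fell. Without BM progenitor replicates 1, 2 and 3, Runx2wt replicates 1, 2 and 3 and Runx2ko replicate 1 in turn, 1, 1, 1, 8, 1, 17 and 26 ribosomal and 2, 1, 2, 3, 2, 4 and 7 glycolysis genes rose, and 0, 0, 0, 10, 0, 1 and 18 cell cycle and 0, 0, 0, 5, 0, 1 and 16 cholesterol genes fell. In the last of these fits 2 glycolysis genes fell. With an estimated correlation the adjusted p was 0.666 for ribosomal, 0.603 for glycolysis, 0.603 for cell cycle and 0.442 for cholesterol genes, and the glycolysis call was lost without Runx2wt replicate 2 (adjusted p = 0.0583). Runx1 was at 59.2 ± 14.0 CPM in Runx2wt and 123.8 ± 20.3 CPM in BM progenitor, a log2 fold change of -1.07 (SE 0.24, edgeR adjusted p = 0.0233). This was lost without BM progenitor replicates 1, 2 or 3 (adjusted p = 0.0594, 0.0798 and 0.0957) and without Runx2wt replicates 1 or 3 (adjusted p = 0.0652 and 0.069). Runx2 itself was 1.56 log2 units higher in Runx2wt without passing (SE 0.52, edgeR adjusted p = 0.0738). It passed with DESeq2 (adjusted p = 0.0193) and without Runx2ko replicate 1 (adjusted p = 0.000127), and with RLE factors, a replicate block or a compared library left out it did not (adjusted p = 0.0763 to 0.207).

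**Figure D2:**
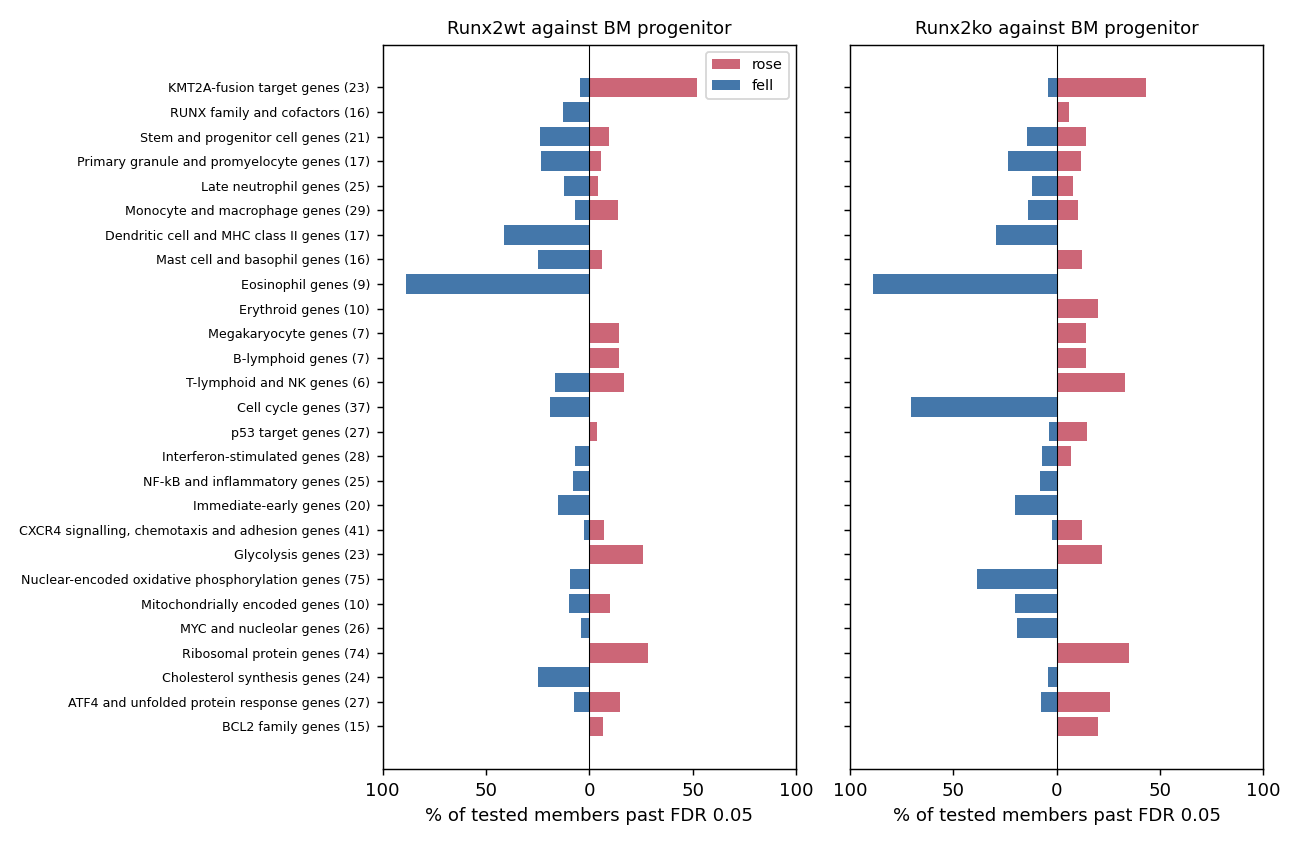
Share of tested members of each gene list that passed at an adjusted p under 0.05, with rises to the right and falls to the left as percentages, for Runx2wt and Runx2ko against BM progenitor; the number tested stands after each name. Eosinophil genes fell for 8 of 9 members in both. Cell cycle genes fell for 7 of 37 in Runx2wt and 26 of 37 in Runx2ko, and for 18 and 29 of 37 without Runx2ko replicate 1. None of these 37 genes passed between Runx2ko and Runx2wt.

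In all, 1513 of 11196 genes passed, 927 higher and 586 lower in Runx2wt, and 5519 genes had groups that did not overlap (49.3%, where chance gives 10% for 3 against 3). The share of passing genes that was higher was 61.3%. Over the alternatives it ran from 52.1% with limma-voom to 69.4% without Runx2wt replicate 2. The count of genes that passed rose to 3256 without Runx2ko replicate 1, which is not among the compared libraries. Leaving out a compared library lowered it, to 331, 267 and 209 for BM progenitor replicates 1, 2 and 3. For Runx2wt replicates 1, 2 and 3 it was 879, 402 and 842. Such a fit also has fewer libraries in a group, so these falls do not show that particular libraries carry the calls.

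The comparison of Runx2ko with Runx2wt asked what loss of Runx2 changes in transformed cells. No gene passed with edgeR, the smallest adjusted p being 0.442, while 886 of 11196 genes had an unadjusted p under 0.05. DESeq2 called 48 genes, 35 higher and 13 lower in Runx2ko, and limma-voom called 0. Genes with groups that did not overlap numbered 1084 (9.7%, where chance gives 10%). Without Runx2ko replicate 1, edgeR called 5 genes. In that fit Itgal, an integrin subunit of leukocytes, was 2.28 log2 units higher (adjusted p = 0.0009), with 168.2, 409.3 and 407.3 CPM in Runx2ko and 82.8, 101.4 and 68.4 CPM in Runx2wt. Hpgd, a prostaglandin-degrading enzyme, had a log2 fold change of -3.30 (adjusted p = 0.0015), with 0.647, 13.7 and 12.7 CPM in Runx2ko and 93.7, 125.0 and 175.3 CPM in Runx2wt. Over all alternatives the adjusted p ran from 3.51e-05 to 0.823 for Itgal and from 2.63e-05 to 0.823 for Hpgd. The others were Cgnl1 and Cd24a, both lower, and Gm1673, which was higher and was chosen after its values were seen. In 50 simulations with Runx2ko drawn at the Runx2wt means, the fit without Runx2ko replicate 1 called 0 to 5 genes (mean 0.6). A count of 5 can thus arise with no true difference.

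**Figure D3:**
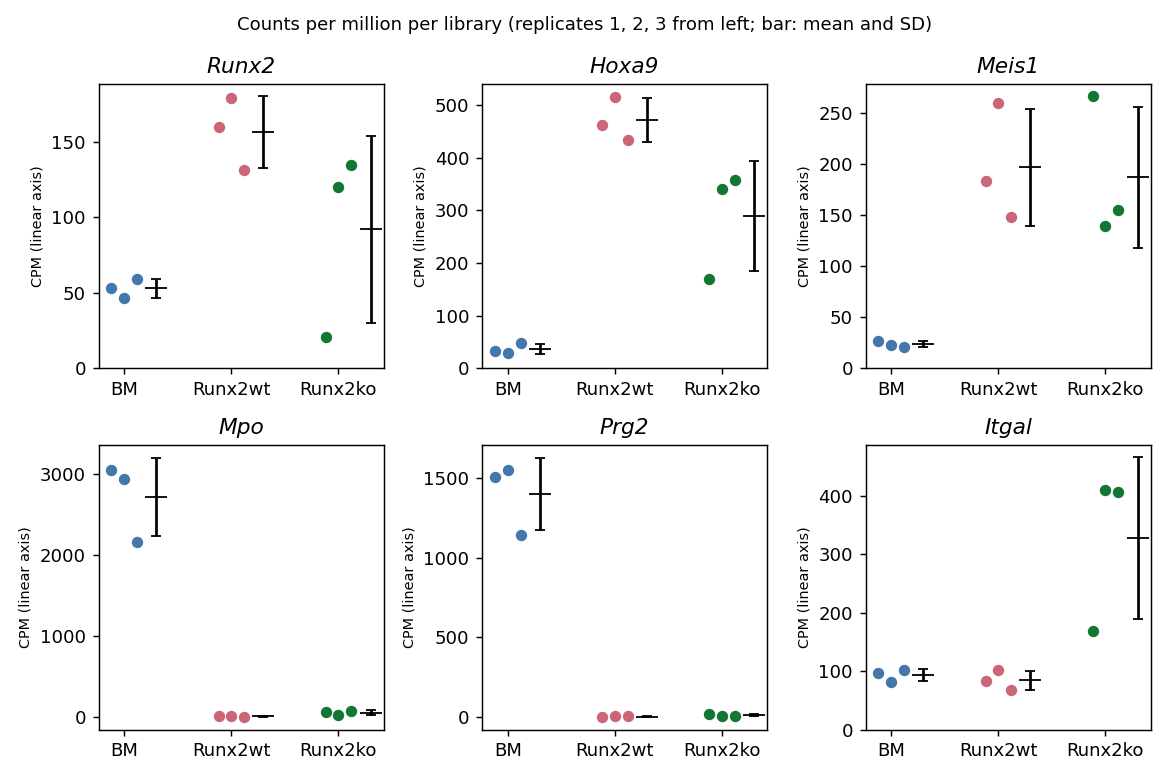
CPM of 6 genes on linear axes, with each point a library (replicates 1 to 3 from left in each group) and the bar giving the group's mean and SD. Runx2 in Runx2ko replicate 1 is at 21.0 CPM, against 120.1 and 134.7 CPM in the other Runx2ko libraries.

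Runx1 had 175.0, 106.9 and 132.5 CPM in Runx2ko and 47.8, 74.8 and 55.1 CPM in Runx2wt, a log2 fold change of 1.22 (SE 0.24) that did not pass in edgeR (adjusted p = 0.511) and passed in DESeq2 (adjusted p = 0.00956); over its alternatives the adjusted p ran from 0.00956 to 0.823. Hoxa10 was at 43.7 ± 12.9 CPM against 131.9 ± 15.6 CPM (edgeR adjusted p = 0.579) and Hoxa9 at 289.1 ± 104.5 CPM against 471.5 ± 41.5 CPM (adjusted p = 0.59). Log2 fold changes of -0.08 for Meis1, -0.07 for Cxcr4, 0.68 for Kit, 0.33 for Elane and 1.89 for S100a8 did not pass either; Runx2ko replicate 1 held 25.6 CPM of Cxcr4, 2.91 CPM of Elane and 39.8 CPM of S100a8. No member of any list passed over all genes, and 23 members of the 27 tested lists, counted per list, did when adjusted over the list alone. By camera, 12 of 27 lists were called, with cell cycle (adjusted p = 3.5e-14), oxidative phosphorylation and KMT2A-fusion target genes lower and eosinophil, ATF4 and mast cell genes higher. None of these calls held with an estimated correlation, where the smallest adjusted p was 0.0744, for ATF4 and unfolded protein response genes. With fry 2 lists were called, both higher. The fry adjusted p was 0.00751 for ATF4 genes (0.0336 without Runx2ko replicate 1) and 0.0223 for eosinophil genes (0.146 without Runx2ko replicate 1). Of 9 eosinophil genes, 4 had 0 counts in every Runx2wt library, so the rise of that list starts near the floor. Without Runx2ko replicate 1, 5 of the 12 calls were lost: stem cell, mast cell and megakaryocyte genes, called higher (adjusted p = 0.472, 0.317 and 0.667, the last now lower), and monocyte and NF-kB genes, called lower (adjusted p = 0.432 and 0.472). That fit called 10 lists. Primary granule, interferon-stimulated, and CXCR4, chemotaxis and adhesion genes were newly called higher by camera (adjusted p = 7.17e-05, 0.00152 and 0.0347). These new calls did not hold with an estimated correlation either (adjusted p = 0.751 for each). Mast cell genes averaged 4.35 log2 units above the Runx2wt mean in Runx2ko replicate 1, and KMT2A-fusion target genes averaged -1.66. Cell cycle genes averaged -0.82, -0.1 and -1.11 in Runx2ko replicates 1 to 3, against 0.44, -0.33 and -0.11 in Runx2wt. Runx2ko replicate 2 thus lay within the Runx2wt range for this list. Without Runx2ko replicate 3 the late neutrophil, cholesterol synthesis and megakaryocyte calls, all higher, were lost (adjusted p = 0.111, 0.396 and 0.114). The cholesterol and NF-kB calls were also lost without Runx2wt replicate 3 (adjusted p = 0.138 and 0.491), and the megakaryocyte call without Runx2wt replicates 1 or 2 (adjusted p = 0.348 and 0.216).

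The comparison of Runx2ko with BM progenitor placed the cells given 4-OHT against the BM progenitor cells, which also differ in culture form and passage. Hoxa9 rose by 2.98 log2 units (SE 0.31, edgeR adjusted p = 0.0015), Hoxa10 by 4.63 and Meis1 by 2.98, and 10 of 23 KMT2A-fusion target genes rose and 1 fell (11 and 1 adjusted over the list alone). Eosinophil genes fell for 8 of 9 members, also adjusted over the list alone, with log2 fold changes of -7.34 for Prg2 and -8.81 for Ear6, and this call held with an estimated correlation (adjusted p = 0.00392, and 0.0174 without Runx2ko replicate 1). Mpo fell by 5.60 log2 units. Cell cycle genes fell for 26 of 37 members (32 adjusted over the list alone), with log2 fold changes of -2.59 for Bub1 and -2.36 for Plk1, which encode mitotic kinases, and oxidative phosphorylation genes fell for 29 of 75 (37 fell and 2 rose adjusted over the list alone), with -1.41 for Cycs, cytochrome c. With an estimated correlation the adjusted p was 0.294 for KMT2A-fusion target and cell cycle genes and 0.332 for oxidative phosphorylation genes. Of 27 ATF4 and unfolded protein response genes 7 rose and 2 fell (10 and 2 adjusted over the list alone), with Trib3 rising by 3.50; camera did not call this list (adjusted p = 0.0666). Without BM progenitor replicates 1, 2 and 3 and Runx2ko replicates 1, 2 and 3 in turn, 8, 9, 8, 14, 9 and 9 KMT2A-fusion target and 3, 4, 3, 10, 7 and 6 ATF4 genes rose, and 10, 11, 12, 29, 32 and 17 cell cycle and 9, 8, 8, 28, 21 and 26 oxidative phosphorylation genes fell. Eosinophil genes fell for 6, 6, 6, 8, 7 and 6 members. Runx2 was 0.80 log2 units higher without passing (adjusted p = 0.309) and passed without Runx2ko replicate 1 (1.26, adjusted p = 0.000815); over all settings the adjusted p ran from 0.000815 to 0.643. In all 1924 genes passed, 1125 higher and 799 lower, a split that was 890 and 989 with limma-voom and 1006 and 956 with the authors' normalized values. The count was 3311 without Runx2ko replicate 1 and 498, 435 and 405 without BM progenitor replicates 1, 2 and 3.

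Whether genes that differ after transformation move back in Runx2ko was read from the log2 fold changes of both comparisons across 11196 genes, which are not independent replicates. Pearson's r was -0.494 and Spearman's rho -0.234. The covariance was -0.56. The Runx2wt libraries enter both comparisons with opposite signs, which gives negative values with no effect at all: 50 simulations of 3 unchanged groups gave r from -0.542 to -0.464, rho from -0.484 to -0.448 and a covariance from -0.142 to -0.111. Real change between Runx2wt and BM progenitor weakens r and rho where Runx2ko stays at the level of Runx2wt. Therefore 50 further simulations, chosen after seeing the data, kept that change and drew Runx2ko at the Runx2wt means. They gave r from -0.219 to -0.134, rho from -0.225 to -0.184 and a covariance from -0.153 to -0.089, and the observed values were more negative than each of these ranges. They called 2001 to 2218 genes between Runx2wt and BM progenitor, against 1513 observed, and why they called more was not tested. The draws added noise to group means that were themselves measured with noise, so their r and rho may lean towards 0. The mean covariance was -0.121 with that change and -0.122 without it. Without Runx2ko replicate 1, r was -0.197 against -0.16 to -0.084 in such simulations and the covariance -0.196 against -0.118 to -0.06, both more negative, whereas rho was -0.032 against -0.169 to -0.134, which was weaker. These simulations called 3771 to 3990 genes, against 3256 observed, and may lean the same way. The simulations drew each gene independently, so libraries whose genes move together could give wider ranges, and the 3 Runx2wt libraries are too few to divide. With no gene called by edgeR between Runx2ko and Runx2wt, none could be called in both comparisons in opposite directions. DESeq2, which called 48 there, called 28 in opposite directions, 7 that were highest and 21 that were lowest in Runx2wt, against 3.78 expected from independent lists, a value that leaves out the shared libraries. Without Runx2ko replicate 1 there were 2, Hpgd and Cgnl1, both higher in Runx2wt than in BM progenitor and lower in Runx2ko than in Runx2wt, against 0.72 expected from independent lists of these sizes over both directions and 0 to 3 in the simulations that kept the change of Runx2wt.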

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

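The fit without Runx2ko replicate 1 for Runx2wt against BM progenitor was chosen after seeing the data; the other settings were fixed before the data were examined. Gene counts stayed within 1.5 times of the reported ones under RLE and upper quartile factors, without the 20 most abundant genes, under both filters, limma-voom and the authors' normalized values, and median shifts of all genes stayed under 0.1 log2 units. For Runx2wt against BM progenitor the count was 3679 with only the 6 libraries compared, 177 against a log2 fold change of 1, 209 to 879 leaving out a compared library and 3256 without Runx2ko replicate 1. For Runx2ko against BM progenitor these were 1262, 161 and 405 to 3311. For Runx2ko against Runx2wt the count of 0 became 48 with DESeq2 and 0 to 5 leaving out a library. The spread shared by all libraries falls when Runx2ko replicate 1 is left out (common dispersion 0.1208 to 0.05635), which goes with the higher counts; otherwise the cause was not tested. List counts of 14, 12 and 11, in the order given in the report, became 1, 0 and 1 with an estimated correlation and 5 and 2 with fry for the first and the second. The 5 were eosinophil, KMT2A-fusion target, dendritic cell, cholesterol synthesis and glycolysis genes, and the 2 were ATF4 and eosinophil genes. The correlation of -0.494 was -0.329 under the strict filter, -0.472 with DESeq2, and -0.559 to -0.197 leaving out a library; genes called in opposite directions became 28 with DESeq2 and 0 to 2 leaving out a library, and the cause was not tested. No pairing by replicate number was seen: deviations from group means correlated at -0.07 to 0.07 between libraries of the same number and at -0.11 to 0.14 between others. With 3 libraries per group this check cannot exclude pairing. With a replicate block the gene counts were 922, 0 and 1120, the list counts 14, 12 and 11, and the correlation -0.54. Among named genes none that passed in either fit changed sign. Values that had not passed changed sign against BM progenitor in Runx2wt for Mef2c (-0.17 to 0.547), Csf1r (-0.19 with the block, and -0.47 to 0.53) and Cdkn1a (-0.548 to 0.049), and between Runx2ko and Runx2wt for Meis1 (-0.42 to 0.172), Elane (-0.518 to 0.912), Cxcr4 (-0.459 to 0.424), Csf1r (-1.521 to 0.017) and Cdkn1a (-0.808 to 0.089), as ranges of log2 fold changes on leaving out a library unless stated, and the cause was not tested. In simulated counts the share of 2-fold changes recovered went from 18.8%, 7.7% and 10.3% to 48.5%, 25.4% and 22.7% without Runx2ko replicate 1; depth was not varied. DESeq2 gave no adjusted p for Mcpt8 and Prss34 in Runx2wt against BM progenitor, which are not counted as lost calls.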

Other observations

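The gene lists, their tests and the splits of the libraries were set out before their results were seen; the tests of what sets Runx2ko replicate 1 apart and of the eosinophil genes, and fits without Runx2ko replicate 1 for Runx2wt against BM progenitor, were chosen after.

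In Runx2wt against BM progenitor, 7 of 75 nuclear-encoded oxidative phosphorylation genes fell and none rose, also adjusted over the list alone, and the list was called by camera (adjusted p = 0.000413) but not with an estimated correlation (adjusted p = 0.626). Of 29 monocyte and macrophage genes 4 rose and 2 fell (7 and 4 adjusted over the list alone), and of 16 RUNX family and cofactor genes 2 fell and none rose, also adjusted over the list alone; camera called neither list (adjusted p = 0.485 for both). Without BM progenitor replicates 1, 2 and 3, Runx2wt replicates 1, 2 and 3 and Runx2ko replicate 1 in turn, 0, 0, 0, 5, 0, 2 and 19 oxidative phosphorylation and 0, 0, 0, 0, 1, 1 and 4 RUNX family genes fell, and 2, 2, 3, 3, 3, 3 and 9 monocyte genes rose. In the last of these fits 1 oxidative phosphorylation gene and 2 RUNX family genes rose and 5 monocyte genes fell. Mast cell and basophil, MYC and nucleolar, and immediate-early genes were called lower by camera (adjusted p = 0.0152, 0.000274 and 0.0227). None of these calls held with an estimated correlation (adjusted p = 0.678, 0.666 and 0.626). The mast cell and immediate-early calls were also lost without Runx2wt replicate 1.

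In Runx2ko replicate 1 the 10 erythroid genes averaged 2.36 and the 7 megakaryocyte genes 3.26 log2 units above the Runx2wt mean, against 0.56 to 0.79 and 0.59 to 0.74 in BM progenitor; these are means of few genes and were not tested. Stem and progenitor genes averaged 2.52 and KMT2A-fusion target genes -1.66, both near BM progenitor (1.81 to 2.10 and -2.17 to -2.07). Meis1 was at 266.2 CPM and Hoxa9 at 168.8 CPM, both above every BM progenitor library.

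A BM progenitor library under the wrong label is argued against, since the highest correlation of this library with BM progenitor was 0.841 and the lowest within BM progenitor was 0.974. Other cells mixed into a culture with at least 10% of its RNA from cells like the other transformed libraries are argued against too. Of 1690 genes at 100 CPM or more in each other transformed library, 26 lay more than 10-fold under their lowest level there. This was 0 for each other transformed library set against the remaining 4 without Runx2ko replicate 1 (1718 to 1772 genes). The values bound a share of RNA and not of cells. A culture with RNA almost wholly from other cells stays open. A candidate explanation is that Runx2 was lost in this library and not in the others, whose Runx2 tags were 120.1 and 134.7 CPM against 21.0 CPM here; with 1 library, and tags that may lie outside the deleted part, this cannot be told apart from a culture of another origin. Expression of Xist also varied within each group. Xist, the RNA of the inactive X chromosome in female cells, was at 0.323, 51.0 and 56.6 CPM in Runx2ko. It was at 0, 0.554 and 21.4 CPM in Runx2wt and 51.3, 0.54 and 57.1 CPM in BM progenitor. The Y-linked gene Ddx3y was at 45.3 to 168 CPM in the 9 libraries. Libraries with Xist at 21.4 CPM or more thus held tags of both, as a mix of male and female cells would. The sex make-up itself was not tested. Of the 9 libraries, Runx2ko replicate 1 was highest for the Y-linked genes Ddx3y (168 CPM), Uty (61.8 CPM), Eif2s3y (51.8 CPM) and Kdm5d (14.2 CPM). Runx2ko replicate 1 thus differed from the rest of its group in Xist, but Runx2wt replicates 1 and 2, which were as low, did not stand apart.

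The fall of eosinophil genes in Runx2wt was not matched by a like median fall in the other lineage lists. The median log2 fold change was -8.86, or -7.56 with its 4 genes at 0 in every Runx2wt library set to their bound. It was -2.74 for mast cell and basophil genes, the lowest of the other 9 lineage lists, and 0.33 for monocyte and macrophage genes. The eosinophil list was singled out after its fall was seen, and a median depends on which genes a list holds. Single genes of other lists, such as Mpo, fell about as far. Whether culture form or the fusion accounts for the fall of eosinophil genes was not tested, since culture form differs with the group.

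Comparisons of 3 against 3 libraries have 10 splits, too few for a share under 0.05. For Runx2wt against BM progenitor the real split gave 1513 genes and the highest other 0, with 1 split as large; for Runx2ko against BM progenitor 1924 and 0, with 1 as large; for Runx2ko against Runx2wt 0 and 0, with all 10 as large. Genes with groups that did not overlap numbered 5519 against 825, 4294 against 1306 and, for Runx2ko against Runx2wt, 1084 against 1538, with 1, 1 and 5 splits as large. List counts did not stand out in this way: the real splits gave 14, 12 and 11 lists, the highest others 14, 13 and 13, and 2, 3 and 5 splits were as large in the order Runx2wt against BM progenitor, Runx2ko against Runx2wt and Runx2ko against BM progenitor.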
